A study of Mus musculus with 2 samples.

How the data were processed

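RNA of 2 cell populations sorted from the small intestinal lamina propria of 8-week-old C57BL/6 mice was measured on 3' expression microarrays, with 1 array for dendritic cells (CD11c+MHCII+) and 1 array for eosinophils (CD11b+, CD11c intermediate, MHCII-, SiglecF+). Neither population had been stimulated, per the labels. Total RNA was extracted with Trizol and turned into fragmented, biotin-labelled cDNA with a commercial amplification system, per the labels' protocols. How many animals contributed cells to each sort is not given in the sources used here.

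The deposited values are linear signal intensities, 1 per probe set, made with MAS5 version 5.0 per the submitters' processing notes. The mean of each array without its lowest and highest 2% of signals was 499.9 in the deposited table, so the 2 arrays share a global scale. The deposited intensities come without detection calls or probe-level background. Scanner files were not used here. The precision of such values is limited by the number of arrays: with 1 array per population there is no replicate error, and no p-value, standard error or call of significance was computed. A difference describes these 2 arrays, not the populations.

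The table held 22690 probe sets, of which 64 were array controls. In the platform annotation, whose symbols can be old, 20393 probe sets had 1 gene, 691 had several and were not named, and 1606 were not listed. Symbols were updated through the Entrez identifier for 20364 of the named probe sets with a RefSeq table of assembly GRCm38.p6. No genome build is named for the values, so no coordinates are given. Where a gene had several probe sets, the one with the highest mean log2 signal stood for it, which gave 12393 genes.

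Signals were put on the log2 scale after a floor. The floor was the median of all signals of both arrays pooled, 134.7 signal units. A signal under it was raised to it, so a ratio with 1 side under the floor is a lower bound, written "at least". Where both sides lay under the floor the gene was taken as not measured and given no ratio. The 95th percentile of a background list (germ cell, lens, hair and olfactory genes) was higher, 207.0 units. A signal between 134.7 and 207.0 units may therefore be background, and a ratio with 1 side in that range may be a lower bound too. A gene was counted as apart at 4-fold or more. Array controls entered neither genes nor lists.

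The spread that the data do allow is that between probe sets of the same gene. Its pooled SD was 0.73 on the log2 scale (1.65-fold), over 4402 probe sets of 1766 genes above the floor on both arrays. It measures disagreement between probe sets, not between animals or preparations.

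A total of 38 gene lists (cell type markers, pathways, RNA quality genes, housekeeping genes and a background list) were fixed before the data were examined. Their choice drew on general knowledge of these cells, including published interest in the IL-1 receptor antagonist of intestinal eosinophils, which may rest on these same arrays. For each list with at least 5 measured members, the median log2 difference was set against 10000 random lists of the same size, matched on mean log2 signal in 20 bins. The percentile is a description of these arrays, not a p-value. Of the 35 lists with a percentile, 6 lay above and 11 below the central 95% of random lists. With 35 lists, a few would lie outside by chance. Some lists share members, so they are not independent of each other.

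The genes named were also set by rule before the data were examined. They are the 8 genes above the floor on both arrays with the largest difference in each direction, the 6 brightest genes above the floor on 1 array only for each array, up to 4 members of each list with the largest difference, and a fixed set: the sort markers, Il1rn, Il1a, Il1b, Il6, Il23a, Il12b, Tgfb1, Aldh1a2, Itgae, Cx3cr1, Ccr3, Epx, Prg2, Il5ra and Il10. Genes named outside this rule are marked as chosen after their values were seen, apart from the members of the closing tests, where it is said when each test was chosen.

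The floor, the count and the random lists were tested on simulated arrays, with 200 of 5389 genes changed and noise of the size of the probe set SD. Of the genes changed 8-fold, 86.0% were counted at 4-fold, against 0.77% of unchanged genes, and 5.0% of unchanged lists fell outside the central 95%. The simulated genes were drawn from those above the floor on both arrays, with noise independent between genes. These shares therefore check the procedure and are not error rates of the 2 real arrays, whose preparation noise is unknown. Alternatives fixed in advance were centring on the median, quantile normalization, loess on mean signal (span 0.3), centring on housekeeping genes, other floors, other rules for the probe set of a gene, and thresholds of 2-fold and 10-fold. Centring on the hybridisation spike controls, and the MHC class II and eosinophil identity lists without the genes of the sort, were added after seeing the data, as were percentiles among random lists of all genes with members under the floor on both arrays kept at 0. Analyses used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.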

Results

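To examine how eosinophils and dendritic cells of the small intestinal lamina propria differ in gene expression, sorted cells of both kinds were profiled on 1 array each. The median signal was 122.0 units on the dendritic cell array and 148.1 units on the eosinophil array, and 47.2% and 52.8% of the probe sets lay above the floor of 134.7 units. Across all 22690 probe sets the log2 signals correlated with Pearson's r = 0.713 and Spearman's rho = 0.719. These coefficients are across probe sets within 1 pair of arrays, and probe sets are not independent replicates. There were no replicate arrays, so every difference below is a value without replicate error and no test was made. The only spread available was that between probe sets of the same gene, with a pooled SD of 0.73 on the log2 scale.

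The 2 arrays differed widely and to a similar extent in both directions. Of 12393 genes, 7994 were above the floor on at least 1 array, and 428 were at least 4-fold brighter in eosinophils while 428 were at least 4-fold brighter in dendritic cells. Of the 5389 genes above the floor on both arrays, 3385 were under 2-fold apart. A further 1632 genes were above the floor on the eosinophil array only and 973 on the dendritic cell array only. The even split of the genes at least 4-fold apart depended on the global scaling of the deposited signals. When the arrays were instead centred on their hybridisation spike controls, which were 2.06-fold brighter on the eosinophil array (median of 18 probe sets), the counts became 161 and 1153. That centring lowers every log2 difference by the same 1.04 before the floor is applied, so random lists move with it, and the sign of a list median on the spike scale does not show how the list stood against other genes. Among genes at least 4-fold apart that had 2 or more measured probe sets, every probe set pointed the same way for 179 of 198 genes brighter in eosinophils and for 173 of 201 genes brighter in dendritic cells, but every probe set was at least 2-fold apart in that direction for only 105 and 94 of them.

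**Figure D1:**
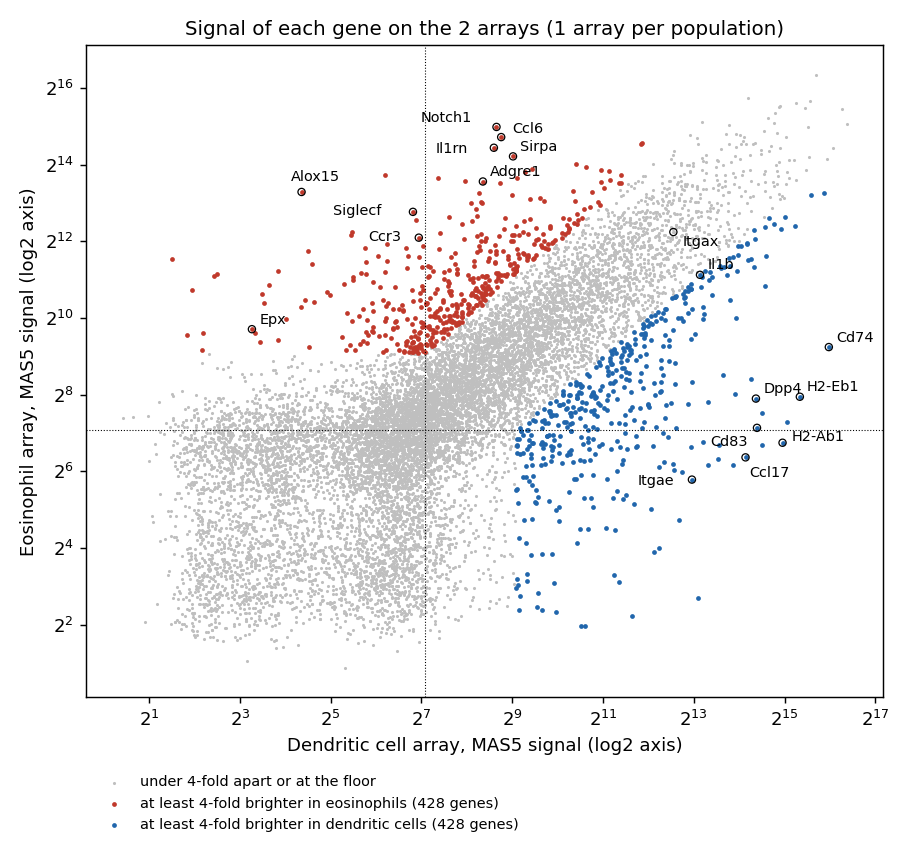
Signal of each of the 12393 genes on the dendritic cell array (x axis) and the eosinophil array (y axis), in MAS5 signal units on log2 axes, with the floor of 134.7 units as dotted lines and 1 array per population. The 428 genes at least 4-fold brighter in eosinophils are red and the 428 at least 4-fold brighter in dendritic cells are blue, with MHC class II genes at the lower right and Il1rn, Siglecf and Alox15 at the upper left.

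Siglecf and the MHC class II chains followed the gates, while Itgax and Itgam separated the arrays far less. Siglecf, the sialic acid-binding lectin used to gate eosinophils, gave 6977 units in eosinophils and 112 units, under the floor, in dendritic cells, at least 51.8-fold apart. The MHC class II chains H2-Aa (34015 units against 155 units), H2-Eb1 (41365 units against 247 units) and H2-Ab1 (31759 units against 108 units) were brighter in dendritic cells by 219-fold, 168-fold and at least 236-fold. Itgax, which encodes CD11c, differed by 1.24-fold (5994 units in dendritic cells and 4846 units in eosinophils). Itgam, which encodes CD11b, gave 227 units in eosinophils and 87.1 units, under the floor, in dendritic cells, at least 1.68-fold apart. Because these genes define the gates, their differences check the labels and are not findings. Among genes above the floor on both arrays, H2-Aa, H2-Eb1 and Cd74 on the eosinophil array gave 0.457%, 0.597% and 0.941% of their dendritic cell signals, and Il1rn on the dendritic cell array gave 1.74% of its eosinophil signal. The eosinophil signal of H2-Aa, 155 units, lay under the 95th percentile of background genes (207 units). Its fold may therefore be a lower bound, and its share may be background.

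Eosinophil identity genes were brighter in eosinophils. Of 12 measured members of the list, 9 were at least 4-fold brighter in eosinophils and none was at least 4-fold brighter in dendritic cells, and the median log2 difference of 3.72 exceeded all 10000 random lists. Without Siglecf, a gene of the sort, 8 of 11 passed 4-fold and the median was 3.70, again above all random lists, in a comparison chosen after seeing the data. The gate selected eosinophils, so this comparison is not independent of the sort. Alox15, an arachidonate lipoxygenase, gave 9996 units in eosinophils against 20.5 units, at least 74.2-fold. Adgre1, which encodes F4/80, was 36.9-fold brighter (12076 units against 327 units), and the eotaxin receptor Ccr3 was at least 32.5-fold brighter (4377 units against 123 units). Il5ra, the IL-5 receptor alpha chain, gave 526 units in eosinophils and lay under the floor in dendritic cells, at least 3.90-fold. Among granule protein transcripts, Epx, the eosinophil peroxidase, gave 837 units, at least 6.21-fold brighter in eosinophils, whereas Prg2, the major basic protein, was under the floor on both arrays with 73.0 units in eosinophils. The list of granule proteins had 6 measured members, with Serpinb2 (1252 units, at least 9.29-fold) and Epx brighter in eosinophils and the lysozyme Lyz2 at least 58.0-fold brighter in dendritic cells. Its median of 0.95 lay at the 98.5th percentile, but the other 6 members lay under the floor on both arrays, and with them kept at 0 the median was 0, at the 49.3rd percentile. The median was 0.23 on the spike scale.

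Beyond identity genes, the largest eosinophil excess measured on both arrays was that of Notch1, a developmental receptor, at 32376 units against 402 units, or 80.5-fold. Both of its probe sets were brighter in eosinophils, by 3.69 and 6.33 on the log2 scale. It was followed by the cytokine signalling inhibitor Socs2 (77.9-fold), the chemokine Ccl6 (62.3-fold), the IL-1 receptor antagonist Il1rn (57.5-fold), the short-chain fatty acid receptor Ffar2 (49.2-fold), Adgre1, Sirpa (36.7-fold) and the paired receptor Pilra (32.7-fold). For Sirpa, the probe sets ranged from 0.88 to 5.20 on the log2 scale. Among genes above the floor in eosinophils only, the brightest were Rflnb at 13545 units, Alox15, Siglecf, the inhibitory receptor Cd300lf at 5988 units, the lactate dehydrogenase Ldhc at 4849 units and the exchanger Slc24a3 at 4597 units.

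Dendritic cell identity genes were mostly brighter in dendritic cells. Of 18 measured members, 9 were at least 4-fold brighter in dendritic cells and 1, Sirpa, was at least 4-fold brighter in eosinophils. The median log2 difference of -2.10 lay below all random lists, and averaging all probe sets of a gene moved it to -1.33. Dpp4, which encodes CD26, gave 21152 units against 239 units (88.6-fold), with a second probe set at -1.61 on the log2 scale. Itgae, which encodes CD103, gave 7961 units and was at least 59.1-fold brighter, and the transcription factor Irf8 gave 4835 units and was at least 35.9-fold brighter. Outside the list, the largest dendritic cell excess measured on both arrays included Cd83 (153-fold), Plbd1 (127-fold), the invariant chain Cd74 (106-fold), the lysosomal thiol reductase Ifi30 (58.7-fold) and Ifitm3 (58.3-fold). Cd83 and Plbd1 gave 141 and 182 units in eosinophils, under the 95th percentile of background genes (207 units), so their folds may be lower bounds. The brightest genes above the floor in dendritic cells only were H2-Ab1, the nuclease Dnase1l3 (23359 units), the chemokine Ccl17 (18045 units), the metallothionein Mt1 (14814 units), H2-Ea (11953 units) and Errfi1 (11773 units), although a second probe set of Errfi1 differed by only -0.41 on the log2 scale.

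Antigen presentation genes were brighter in dendritic cells. Of 10 measured MHC class II presentation genes, 9 were at least 4-fold brighter in dendritic cells, and the median log2 difference of -5.95 lay below all random lists. The list holds H2-Aa, H2-Ab1 and H2-Eb1, which belong to the gate. Without them, a comparison also chosen after seeing the data, 6 of 7 passed 4-fold and the median was -5.04, again below all random lists. The cells were sorted on MHC class II itself, so other genes of the list can follow the gate. Neither comparison is independent of the sort. MHC class I genes differed less: 1 of 12, the peptide transporter Tap1 (5.31-fold), passed 4-fold, and 7 passed 2-fold, all brighter in dendritic cells. H2-D1 and H2-K1 differed by 3.35-fold and 3.28-fold, and members of this gene family share sequence, so their probe sets may not tell them apart, and for both genes another probe set was under 2-fold apart. The class I median of -1.11 lay at the 0.43rd percentile. Of 12 measured costimulatory and coinhibitory genes, 5 were at least 4-fold brighter in dendritic cells and none in eosinophils, with Cd83, Pvr (at least 41.2-fold), Cd86 (at least 25.2-fold) and Cd40 (at least 5.15-fold) the furthest apart. Probe sets of Pvr ranged from -5.36 to 0.56 on the log2 scale, and a second probe set of Cd40 differed by only -0.68. Other members, chosen after their values were seen, were above the floor on both arrays: Cd80 (2748 units in eosinophils, 1448 units in dendritic cells), Icosl (6419 units and 4911 units), Cd274, the ligand PD-L1 (5522 units and 6255 units), Pdcd1lg2 (737 units and 512 units) and Lgals9 (1003 units and 253 units). Of the list, only Lgals9 was at least 2-fold brighter in eosinophils. The list median of -0.34 lay at the 7.84th percentile.

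IL-1 family genes differed in opposite directions. Il1rn, the secreted antagonist of the IL-1 receptor, gave 22225 units in eosinophils and 387 units in dendritic cells, and its 3 probe sets differed by 4.05 to 5.85 on the log2 scale. Il1a gave 574 units in eosinophils and lay under the floor in dendritic cells, at least 4.26-fold. Il1b was 4.03-fold brighter in dendritic cells (9003 units against 2236 units), and the inflammasome sensor Nlrp3 was at least 3.82-fold brighter there (515 units). Of 13 measured members, 2 were at least 4-fold brighter in eosinophils and 1 in dendritic cells. The list median of 0.58 lay at the 96.1st percentile, inside the central 95%, and was -0.30 after centring on the spike controls. Il1rn was on the list partly because of published work that may use these arrays, so the list is not independent evidence of its direction.

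Genes for factors that steer T helper 17 and regulatory T cells did not shift as a group. Of 13 measured members, 3 were at least 4-fold brighter in dendritic cells and none in eosinophils, and the median of -0.023 lay at the 19.0th percentile. The 3 were Il1b, the retinal dehydrogenase Aldh1a2 (1174 units, at least 8.71-fold) and Tgfb1 (1469 units against 202 units, 7.26-fold). The retinol dehydrogenase Rdh10 was 3.66-fold brighter in eosinophils (588 units against 160 units), short of the 4-fold mark. Tgfb2, chosen after its values were seen, was also brighter in eosinophils (439 units, at least 3.26-fold), with probe sets at 1.13 and 1.70 on the log2 scale. Il6 and Il10 were under the floor on both arrays. Il12b reached 173 units in dendritic cells and Il23a reached 150 units in eosinophils, both close to the floor, so no difference was detectable for them at this brightness.

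**Figure D2:**
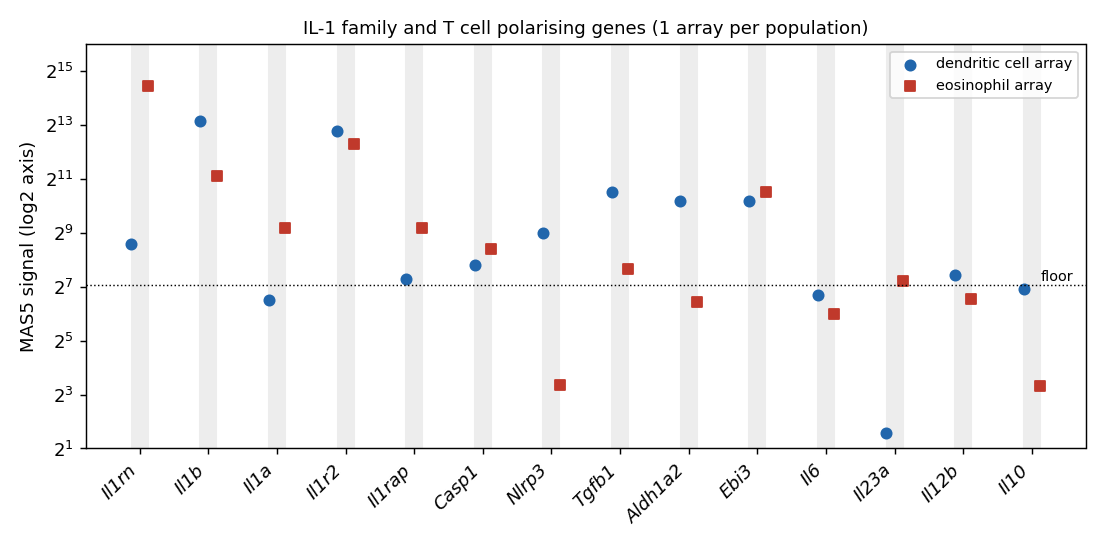
MAS5 signal (y axis, log2) of 14 genes of the IL-1 family and of T cell polarising factors on the dendritic cell array (circles) and the eosinophil array (squares), 1 array each, with the floor of 134.7 units as a dotted line. Il1rn lies at 22225 units in eosinophils against 387 units in dendritic cells, Il1b at 2236 units against 9003 units, and Il6 and Il10 lie under the floor on both arrays.

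Type 2 cytokines and their receptors had 7 measured members, of which only Il4 passed 4-fold, at 846 units in eosinophils against 146 units (5.79-fold). The growth factor Csf2 (533 units), Il5ra and Il13ra1 (453 units) were brighter in eosinophils by at least 3.95-fold, at least 3.90-fold and 2.70-fold, with probe sets of Il13ra1 from -0.40 to 1.84 on the log2 scale. Csf2ra and Il4ra, chosen after their values were seen, were brighter in dendritic cells by 2.24-fold and 1.94-fold, although probe sets of Csf2ra ranged from -1.16 to 1.14. The list median of 1.43 lay at the 99.6th percentile, but at the 61.1st percentile with a floor at the 25th percentile of signals, and it was 0.15 on the spike scale. The other 8 members, among them Il5, Il13, Il9, Il25 and Il33, chosen after their values were seen, lay under the floor on both arrays, and with them kept at 0 the median was 0. Of 12 other inflammatory cytokines, Csf1 (1798 units, at least 13.3-fold) and Il16 (4.12-fold) were brighter in eosinophils, and the median of -0.12 lay at the 9.65th percentile. Probe sets of Csf1 ranged from -0.52 to 3.74, and a second probe set of Il16 differed by only 1.36. Mif and Tnf were brighter in dendritic cells by 3.90-fold and 3.63-fold.

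Chemokines fell into separate sets. Of 17 measured, 4 were at least 4-fold brighter in eosinophils, led by Ccl6 (26943 units against 432 units) and Ccl3 (7353 units against 293 units, 25.1-fold). Another 4 were at least 4-fold brighter in dendritic cells, led by Ccl17 (at least 134-fold) and Ccl22 (4781 units, at least 35.5-fold). The list median was 0.0015, at the 21.9th percentile, and became -0.85 on the spike scale. Of 13 measured chemoattractant receptors, 6 were at least 4-fold brighter in eosinophils, including Ccr3, Ccr1 (2599 units, at least 19.3-fold) and the leukotriene B4 receptor Ltb4r1 (2273 units, at least 16.9-fold). A second probe set of Ccr1 differed by only 1.79 on the log2 scale. Ccr7, the lymph node homing receptor, was at least 21.9-fold brighter in dendritic cells (2945 units), as was the gut homing receptor Ccr9 by 7.18-fold, although a second probe set of Ccr9 differed by only -0.37 on the log2 scale. The receptor median of 0.21 lay at the 58.1st percentile and moved up to 2.44 with the floor set from background genes (207 units). A higher floor brings no difference further from 0, so this rise reflects dim members that dropped out of the list. Cx3cr1 was under the floor on both arrays.

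Fc receptors and paired immunoglobulin-like receptors were brighter in eosinophils as a group. Of 13 measured, 8 were at least 4-fold brighter in eosinophils and none in dendritic cells, and the median of 2.83 exceeded all random lists. They included the signalling chain Fcer1g (9854 units against 309 units, 31.9-fold), Fcgr3 (26.5-fold), Fcgr2b (at least 22.8-fold) and Cd300lf (at least 44.4-fold). Eicosanoid genes had 13 measured members, with 4 at least 4-fold brighter in eosinophils and none in dendritic cells: Alox15, the leukotriene A4 hydrolase Lta4h (3769 units, at least 28.0-fold), Pla2g7 (8233 units, 25.6-fold) and Alox5ap (4.37-fold). Probe sets of Lta4h ranged from 0.57 to 4.81 on the log2 scale, and the list median of 0.49 lay at the 92.2nd percentile, with a change to -0.052 on the spike scale. NADPH oxidase and oxidative genes had 13 measured members and a median of 0.996, at the 99.4th percentile, which became -0.044 on the spike scale. In that list only Ncf1 passed 4-fold (8.52-fold), and its second probe set differed by only 0.49. Cat, Hvcn1 and Rac2 were brighter in eosinophils by 3.98-fold, 2.66-fold and 2.54-fold. Gpx1 and Sod2, chosen after their values were seen, were brighter in dendritic cells by 2.33-fold and 2.27-fold, with another probe set of Sod2 at -0.49.

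Pattern recognition genes had 13 measured members with a median of 0.14 at the 46.1st percentile, which became -0.68 on the spike scale. Tlr4, the lipopolysaccharide receptor, was at least 12.7-fold brighter in eosinophils (1712 units), whereas the beta-glucan receptor Clec7a (at least 38.4-fold) and the lipopolysaccharide co-receptor Cd14 (at least 19.6-fold) were brighter in dendritic cells. Tlr3 was 9.87-fold brighter in dendritic cells by 1 probe set, but a second pointed the other way at 0.85. Of 15 integrins and adhesion receptors, Itgae and Itgb7 (5.78-fold) were brighter in dendritic cells and Pecam1 (at least 4.80-fold) in eosinophils, while Cd9 was 3.89-fold brighter in eosinophils. The adhesion median of -0.28 lay at the 13.5th percentile.

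NF-kappaB target, immediate early and heat shock genes were brighter in dendritic cells as groups. Of 14 measured NF-kappaB target genes, 7 passed 4-fold, all brighter in dendritic cells, among them Cd83, Traf1 (at least 31.8-fold), Rel (12.1-fold) and Nfkbie (7.08-fold), and the median was -2.07, below all random lists. Cd83 is also on the costimulation list and Traf1 on the dendritic cell identity list, so these lists are not independent results. Of 19 measured immediate early genes, which also respond to tissue dissociation, 9 were at least 4-fold brighter in dendritic cells, including Nr4a2 (20.4-fold), Fosb (at least 17.2-fold) and Dusp2 (at least 6.46-fold). Egr2 alone was at least 4-fold brighter in eosinophils (9.18-fold), and the median was -1.40 at the 0.01st percentile. Heat shock genes had a median of -1.34 at the 0.11th percentile, with 5 of 11 past 4-fold: Hspa1b (8.68-fold), Hspb1 (at least 7.76-fold), Hsph1 (-2.32 on the log2 scale), Hspa8 (4.58-fold) and, chosen after its value was seen, Hspe1 (-2.07 on the log2 scale), all brighter in dendritic cells. Hspa1b has a near-identical copy, Hspa1a, so its value is uncertain, and its second probe set differed by only -0.82. Interferon response genes had 7 measured members and a median of -1.28 at the 0.09th percentile, with Oasl1 (7.48-fold) past 4-fold and Mx1, Stat2 and Irf7 apart by at least 2.73-fold, at least 2.58-fold and 2.43-fold. The other 7 of 14 members lay under the floor on both arrays, and with them kept at 0 the median was 0, at the 47.6th percentile. The list lay at the 4.34th percentile, inside the central 95%, when all probe sets of a gene were averaged.

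Cell cycle and ribosomal protein genes were also brighter in dendritic cells as groups, whereas oxidative phosphorylation genes lay inside the range of random lists. Of 16 measured cell cycle genes, 2 passed 4-fold, Rrm2 (7.54-fold) and Top2a (at least 4.70-fold), Birc5 and Pcna reached at least 3.53-fold and 3.28-fold, and the median of -0.83 lay below all random lists. The cell cycle median became -0.37, at the 1.70th percentile, with the floor set from background genes. By the probe set that stood for each gene, all 16 measured cytosolic ribosomal protein genes were brighter in dendritic cells, 11 of them by at least 2-fold and 4 by at least 4-fold, with a median of -1.40 at the 0.06th percentile. Rplp0 (8.80-fold), Rpl8 (6.87-fold), Rps19 (6.63-fold) and Rps6 (at least 4.35-fold) led this list. Other probe sets pointed the other way for Rps6 (0.39) and, chosen after their values were seen, for Rpl27 (0.47), Rps18 (0.45) and Rps9 (0.035). Of 25 oxidative phosphorylation genes, 2 passed 4-fold, Cycs (4.08-fold) and Cox4i1 (4.01-fold), and Cox6c and Ndufv1 differed by 3.90-fold and 3.68-fold, all brighter in dendritic cells. Probe sets ranged from -2.03 to -0.86 on the log2 scale for Cycs and from -2.01 to -0.98 for Ndufv1. In all, 10 members were at least 2-fold brighter in dendritic cells, 13 were under 2-fold apart, and 2, Uqcrb (2.24-fold) and Uqcrc1 (2.13-fold), chosen after their values were seen, were brighter in eosinophils. The oxidative phosphorylation median of -0.53 lay at the 3.44th percentile, inside the central 95%. Housekeeping genes had a median of -0.090 at the 40.6th percentile, although Eef2 differed by 9.50-fold in favour of dendritic cells and Tbp by 2.43-fold in favour of eosinophils. The 3' over 5' signal ratio of the Gapdh controls was 6.58 in dendritic cells and 9.81 in eosinophils, and that of the Actb controls was 9.002 and 6.38. By this ratio the 2 controls ranked the RNA samples in opposite order, and the 3' signal was well above the 5' signal on both arrays. The 3' over middle ratio was 2.65 and 3.09 for Gapdh and 4.13 and 4.13 for Actb, so it was higher in eosinophils for Gapdh only.

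**Figure D3:**
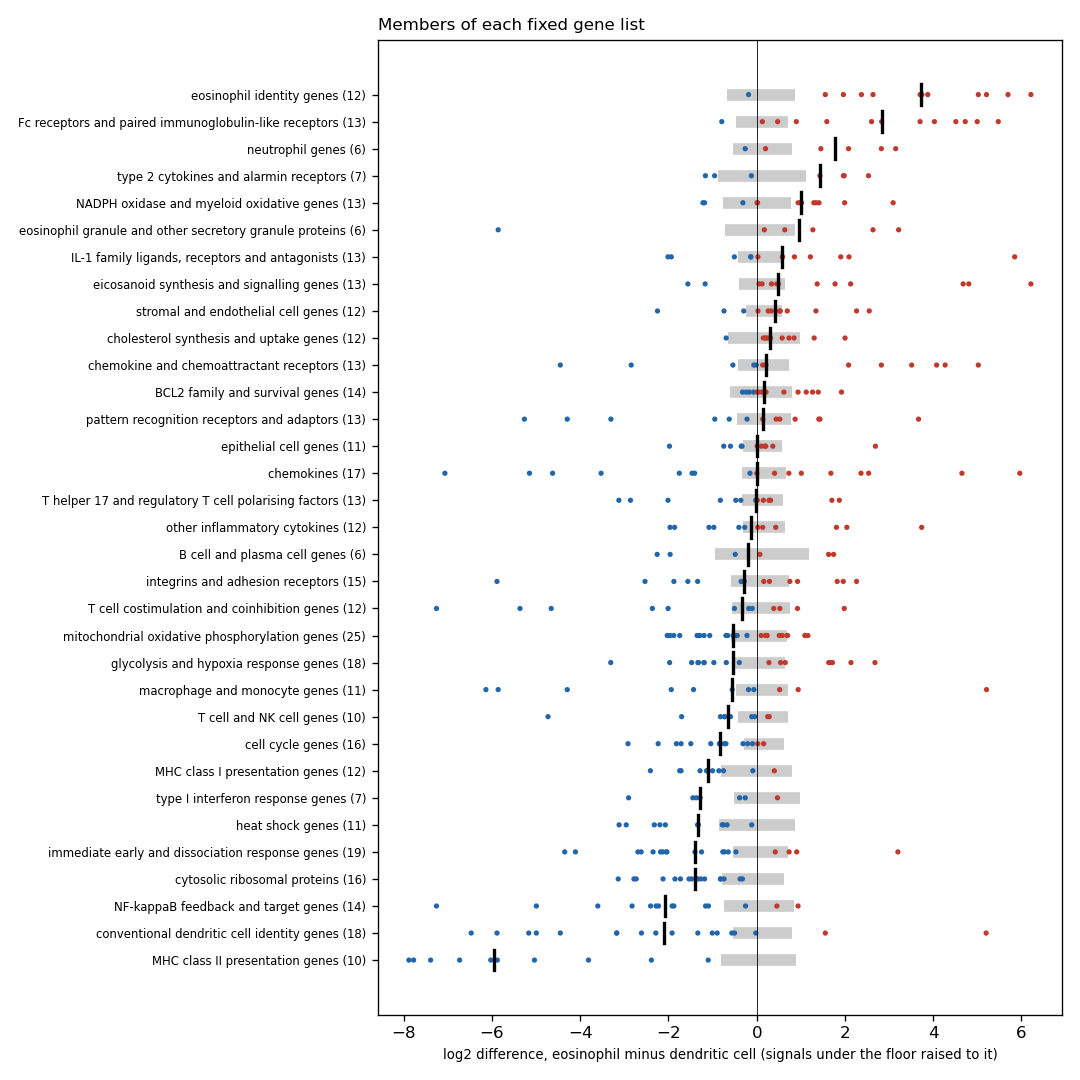
Log2 difference, eosinophil minus dendritic cell (x axis), of each measured member of the fixed gene lists with at least 5 measured members, without the housekeeping and background lists (points, red above 0 and blue below, number in brackets), with the list median as a black bar and the central 95% of matched random list medians as a grey band. Eosinophil identity genes and Fc receptors have the highest medians, 3.72 and 2.83, and MHC class II genes the lowest, -5.95.

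Markers of other cell types went in both directions. Macrophage and monocyte genes had 11 measured members, with Lyz1 (at least 70.3-fold), Lyz2 (at least 58.0-fold) and Cd14 at least 4-fold brighter in dendritic cells and Adgre1 in eosinophils. Of other members, chosen after their values were seen, Cd68 (2573 units) and Csf1r (1121 units) were brighter in dendritic cells by 3.83-fold and 1.47-fold, and Mertk (258 units) and Cd163 (193 units) in eosinophils by at least 1.92-fold and at least 1.43-fold. Lyz1 and Lyz2 are near-identical copies that probe sets may not separate, and another probe set of Lyz1 differed by only -0.02. The list median of -0.56 at the 1.40th percentile moved to the 22.4th percentile with a floor at the 25th percentile of signals, and to 0, at the 43.6th percentile, with the 6 members under the floor on both arrays kept. Neutrophil genes had 6 measured members with a median of 1.77, above all random lists, but 7 others lay under the floor on both arrays, and with these kept at 0 the median was 0, at the 48.9th percentile. Mmp9 (at least 8.87-fold), Fpr2 (7.08-fold) and Cxcr2 (at least 4.23-fold) were brighter in eosinophils, as was Mmp8 by at least 2.74-fold. The list lay at the 96.3rd percentile with the lower floor. T cell and NK cell genes had a median of -0.66 at the 0.49th percentile, or the 2.51st percentile without a floor, with only Cd8a past 4-fold (3732 units in dendritic cells, 26.5-fold). Of 19 members, 9 lay under the floor on both arrays, and with these kept at 0 the median was 0, at the 48.9th percentile. Among the 9, chosen after their values were seen, were Cd8b1, Cd3d, Cd3g, Cd4 and Cd2, and the source of the Cd8a signal was not tested. Thy1, Klrk1 and Cd3e gave 438, 238 and 557 units in dendritic cells, against 9.57, 76.6 and 336 units in eosinophils. Of the B cell and plasma cell genes, Igha passed 4-fold in dendritic cells (643 units, at least 4.77-fold), Sdc1 was at least 3.89-fold brighter there, Xbp1 and Prdm1 were brighter in eosinophils by 3.35-fold and at least 3.09-fold, and the median of -0.21 lay at the 21.5th percentile. Probe sets ranged from -2.26 to -0.92 for Igha, from -1.96 to -0.075 for Sdc1 and from 0.47 to 2.05 for Xbp1. Epithelial genes had 11 measured members and a median of 0.012 at the 24.3rd percentile, which became -0.77 on the spike scale, with Krt18 (870 units) at least 6.45-fold brighter in eosinophils and Cldn7 (530 units) at least 3.93-fold brighter in dendritic cells. Stromal and endothelial genes had a median of 0.42 at the 89.9th percentile, which became -0.22 on the spike scale, with Pdgfra (789 units) and Pecam1 (647 units) brighter in eosinophils and Vwf (640 units) in dendritic cells.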

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

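Signals outside the gene comparison are given as values, and no cause was tested for them. The 18 hybridisation spike probe sets, which detect control transcripts added at hybridisation, were brighter on the eosinophil array by a median of 2.06-fold, with a range of 1.58-fold to 3.31-fold. The control probe set for the mouse B1 repeat gave 11993 units on the eosinophil array and 2747 units on the dendritic cell array, a ratio of 4.37. The B2 repeat control gave 67072 units and 39539 units, a ratio of 1.70. Of the 1555 probe sets without a gene name in the annotation used here and outside the controls, 778 were above the floor on either array, and 46 were at least 4-fold brighter in eosinophils while 27 were at least 4-fold brighter in dendritic cells.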

How the results depend on the processing

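No paired analysis was possible because each population has 1 array, and for the same reason no replicate could be left out. Counts at 4-fold moved by under 1.5 times under centring on the median, quantile normalization, loess, centring on housekeeping genes, the floor from background genes and the 3 other rules for the probe set of a gene: they ran from 322 to 467 for eosinophils and from 326 to 476 for dendritic cells, against 428 and 428. A floor at the 25th percentile (41.4 units) gave 844 and 665 and no floor gave 1901 and 1460, since fewer signals are then held at the floor. A 2-fold threshold gave 1519 and 1241, and a 10-fold threshold gave 105 and 124. Centring on the hybridisation spikes, chosen after seeing the data, gave 161 and 1153, which moved the eosinophil share from 50% to 12.3%. The other scalings shifted the median measured gene by -0.15 (loess) to 0.090 (housekeeping) on the log2 scale. Of 385 values of the 35 list medians under the settings chosen in advance, 362 stayed within the probe set SD of 0.73 and 23 moved further, and no list outside the central 95% changed sign, although 6 of them reached 0. The eosinophil identity median became 2.64 with members under the floor on both arrays kept at 0 and 2.95 on the spike scale. The dendritic cell identity median became -1.33 with probe sets averaged. The MHC class II median became -5.04 without the genes of the sort, a setting chosen after seeing the data, because the members left out were among the furthest apart. On the spike scale the IL-1 family median became -0.30, the T helper 17 factor median -0.89, and the NADPH oxidase median reversed to -0.044, which the common shift of 1.04 sets and which does not place a list among other genes. For the other medians that moved, apart from that of the chemoattractant receptors, the cause was not tested. Of the 17 lists outside the central 95%, 11 stayed outside under all 11 alternatives for which percentiles were computed. The exceptions were the macrophage, neutrophil, T and NK cell, type 2 cytokine, granule protein and interferon lists. With members under the floor on both arrays kept at 0, all 6 had a median of 0, between the 43.6th and 49.3rd percentiles (a percentile added after seeing the data). A median of 0 was also found for 10 of the lists inside the central 95%, because many of their members lay under the floor. Ties at 0 draw these percentiles to the middle, so they say little. Under the other alternatives the 6 exceptions lay at the 22.6th, 96.3rd, 2.51st, 61.1st, 93.3rd and 4.34th percentiles at their least extreme. Of 1568 such values of the 157 named genes, 1426 stayed within the probe set SD, 140 moved further and 2 reversed. Both were of Tlr3, at 0.63 with probe sets averaged and 0.85 without the _x_at and _s_at probe sets, since its probe sets oppose each other. The correlation of the arrays was 0.75 above the floor. Dim signals limit the rest: 4399 genes lay under the floor on both arrays, and no difference was detectable for them.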

Other observations

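Some gene groups were not described above. Glycolysis and hypoxia response genes split: the transporter Slc2a3 (6.41-fold) and the transcription factor Hif1a (4.40-fold) were brighter in eosinophils, whereas the enzymes Pfkp (9.90-fold) and Pgk1 (3.93-fold) were brighter in dendritic cells, and the list median of -0.54 lay at the 2.86th percentile. Probe sets of Pfkp ranged from -3.31 to -0.12, those of Slc2a3 from 0.21 to 2.81 and those of Hif1a from 0.80 to 2.69. Cholesterol synthesis genes had 12 measured members with a median of 0.31 at the 58.9th percentile, which became -0.73 on the spike scale. Fdft1 (at least 4.004-fold), Msmo1 (2.47-fold), Dhcr7 (1.80-fold) and Nsdhl (1.66-fold) were the furthest apart, all brighter in eosinophils, although a second probe set of Fdft1 differed by 0.65. Survival genes of the BCL2 list had 14 measured members, none 4-fold apart, with a median of 0.16 at the 53.7th percentile that became -0.77 on the spike scale. Xiap (3.79-fold), Bcl2 (at least 2.63-fold), Pim1 (2.40-fold) and Pmaip1 (2.18-fold) were the furthest apart, all brighter in eosinophils, although a second probe set of Pim1 differed by -0.64 and probe sets of Xiap ranged from 0.42 to 1.92.

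Lists with under 5 measured members have values only. Plasmacytoid dendritic cell genes had 3, with Ccr9 at 1578 units, Tcf4 at 980 units and Bst2 at 253 units in dendritic cells, against 220, 335 and 7.67 units in eosinophils. Probe sets ranged from -1.55 to 0.47 for Tcf4 and from -2.84 to -0.37 for Ccr9. Mast cell and basophil genes had 3, with Kit at 291 units and Tpsab1 at 157 units in dendritic cells and Gata2 at 226 units in eosinophils, a difference of 0.75 on the log2 scale, with a second probe set at 3.08. Erythrocyte genes had 1, Hba-a2, at 2985 units in eosinophils and 707 units in dendritic cells. The background list of germ cell, lens, hair and olfactory genes had 31 of 43 members under the floor on both arrays and a median of 0.47 at the 94.96th percentile, which became -0.17 on the spike scale. Of its members, 10 lay above the floor on the eosinophil array and 3 on the dendritic cell array. A dim signal above the floor on the eosinophil array alone is therefore weak evidence of expression. The background member furthest apart was Ldhc, at 4849 units in eosinophils and 44.0 units in dendritic cells, with a second probe set that differed by 2.70. The next were Tshb (323 units), Vmn2r1 (241 units) and Cryba1 (215 units), all in eosinophils. Among all genes, 1 had probe sets at least 4-fold apart in opposite directions: Runx1, chosen after its values were seen, with probe sets from -2.76 to 2.55.

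In the tests that follow, those of neutrophils, macrophages, monocytes, the brightness trend and RNA integrity were chosen only after the result was seen, while those of other probe sets and of the 3 target gene lists were stated beforehand. Mmp9, Fpr2, Cxcr2 and Mmp8, known from neutrophils, were brighter on the eosinophil array. Neutrophils, which the gate on SiglecF should remove, would also make their abundant transcripts brighter there, but of 7 of these (S100a8, S100a9, Ngp, Camp, Ltf, Lcn2 and Csf3r) 6 lay under the floor on both arrays and S100a8 differed by -0.26. With the floor at the 25th percentile of signals their median difference was 0.017 (SD 0.82 across the 7), with S100a9 and Lcn2 the highest at 1.17 and 1.15. The 4 genes differed by 2.82 to 3.85. These values argue against neutrophils as the main source, while such dim signals leave a small share open. The 7 come from the same list as the 4 and their signals had been seen, so the comparison is not independent of the pattern. Hybridisation of single probe sets to other transcripts stays open, since only 1 other measured probe set of these genes exists, for Mmp9, which was also at least 4-fold brighter in eosinophils. Expression by the eosinophils themselves was not tested.

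Lyz1, Lyz2 and Cd14 were brighter on the dendritic cell array, and macrophages can pass a gate on CD11c and MHC class II. Of 5 abundant macrophage transcripts, C1qb was brighter there by at least 2.70-fold (with another probe set at -0.28), C1qa differed by -0.19, and C1qc, Apoe and Mrc1 lay under the floor on both arrays. With the lower floor their median was -0.10 (SD 2.06) and the furthest -3.13, against -4.72 to -6.44 for Lyz1, Lyz2 and Cd14. That median is the value of Apoe, which lay under the floor of 134.7 units on both arrays. C1qa and C1qb pointed to the dendritic cell array, and C1qc and Mrc1 the other way. With most of these signals dim and their differences far apart, the test cannot decide, so macrophages stay open. Other markers, chosen after their values were seen, went both ways, with Cd68 and Csf1r (another probe set at -0.015) brighter in dendritic cells, Mertk and Cd163 brighter in eosinophils, and Fcgr1, Cx3cr1 and Trem2 under the floor on both arrays. Monocytes stay open too, since Ccr2 gave 162 units, close to the floor, and the Ly6c genes had no named probe set in the annotation used here, and expression by the dendritic cells was not tested.

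All 16 measured ribosomal protein genes were dimmer on the eosinophil array by the probe set that stood for each, although other probe sets of Rps6, Rpl27, Rps18 and Rps9 pointed the other way. If a trend of the difference with brightness were the whole cause, loess would remove it, but loess moved the list median only from -1.40 to -1.02, at the 0.18th percentile and below the central 95% of random lists, -0.58 to 0.88. RNA integrity cannot be told apart from a difference between the cell types. The Gapdh 3' over 5' ratio was 1.49 times that of dendritic cells in eosinophils, but the Actb ratio was 0.71 times that of dendritic cells. The 3' over middle ratios in dendritic cells and eosinophils, 2.65 and 3.09 for Gapdh and 4.13 and 4.13 for Actb, do not settle it either. A difference between the cell types themselves stays open and untested.

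3 hypotheses came from single genes with a large eosinophil excess, and each was tested on other target genes of the same pathway, with the genes already seen left out. The first came from Socs2. Socs2 and Pim1 (only 2.40-fold, with a second probe set at -0.64) are targets of STAT5, which acts downstream of IL-5, IL-3 and GM-CSF. Among 8 other measured STAT5 targets, 5 were at least 2-fold brighter in eosinophils (Cish at 8.24-fold, Ccnd2 at 4.22-fold, Pim2 by at least 3.76-fold, Ccnd3 at 3.25-fold and Spry2 at 2.89-fold) and 2 in dendritic cells (Pim3 at 4.25-fold and Socs3 at 2.23-fold). Probe sets ranged from 0.29 to 2.26 for Ccnd2, from -2.09 to 0.29 for Pim3 and from -1.16 to -0.36 for Socs3. The median of the 8 STAT5 targets, 1.62, lay at the 99.95th percentile. Stronger STAT5 signalling in eosinophils would give this in these 2 arrays, although cell type differences in the same genes may also account for it. With Socs1, under the floor on both arrays, kept at 0 the list lay at the 99.97th percentile. The target lists were not run under the other floors, scalings and probe set rules or on the spike scale. Cyp1b1 (3613 units, at least 26.8-fold, with another probe set at 0.77) and Nqo1 (2868 units, at least 21.3-fold), both chosen after their values were seen, are targets of the aryl hydrocarbon receptor. Of 7 other measured targets, Ahrr (at least 8.97-fold) and Tiparp (4.02-fold) were brighter in eosinophils, but Serpinb9 (at least 18.0-fold), Scin (at least 11.4-fold) and Nfe2l2 (2.27-fold) were brighter in dendritic cells, and the median of -0.15 at the 18.37th percentile does not decide the question. For Notch1, 4 of 10 other Notch targets were measured, only Nrarp passed 2-fold (at least 2.40-fold, with another probe set at 0.66), and their median was 0.50, or 0 with the 6 under the floor kept. With under 5 measured members no percentile was taken, which leaves that hypothesis undecided as well.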
